A study of Caenorhabditis elegans with 139 samples.

How the data were processed

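Messenger RNA of 139 single embryos, 1 embryo per library and no pooling, was measured by CEL-Seq per the labels. The authors deposited 1 table of raw counts per gene and embryo, with 20784 lines for 20687 genes, 92 spike-in RNAs and 5 counters of reads that name no gene, and applied no normalization to it. Per the labels the upstream tools were CASAVA 1.8, Bowtie2 2.1.0 and HTSeq 0.5.4p3, with no role or order given, and the genome build is not given in the sources used here. The labels name no molecular identifiers, so counts are counts of reads after amplification, and intervals and floors cover counting error only. All counts are whole numbers. Among 109 pairs of embryos with the same labelled time the lowest chi-square per degree of freedom was 2.63. Amplification can raise it, so it cannot show separate embryos. Reads with more than 1 alignment were counted in a separate line that holds 0 reads, so reads shared by members of a gene family may have been placed at 1 locus.

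Gene symbols and chromosomes were taken from Ensembl release 115, with 20083 gene lines matched to 1 gene, 10746 of them with a symbol other than the sequence name, and 20086 placed on a chromosome, 2745 on the X. A total of 1912 genes had no count in any embryo. Counts of genes were used without the spike-ins and the counters. The 170 lincRNA lines among the genes were kept. CPM values are gene counts scaled to the same total of gene counts in each embryo.

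The 7 time windows, the comparisons, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. Per comparison of consecutive windows the rule names the 6 called genes with the largest rise and the 6 with the largest fall among those with a mean of at least 50 CPM in the higher window, and, from the 6 lists with the smallest p, the 2 called members with the largest absolute log2 fold change among those with a mean of at least 20 CPM in the higher window. A set of 20 marker genes is named whatever their values. Genes without a symbol are named by their sequence name. Where 5 or fewer members of a list rose or fell they are named too, chosen after their values were seen.

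Consecutive windows were compared with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr with its minimum count of 10, quasi-likelihood F-test), with only the embryos of the 2 windows in each fit. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a fold of at least 2. Differences among all 7 windows were tested with the same tool over 6 coefficients, without a fold threshold. The 21 gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over all 108 tests of lists with at least 5 tested members, and again with the correlation estimated from the data. The lists cover maternal oocyte-to-embryo regulators, germline P granule and small RNA factors, DNA replication and mitosis, early zygotic lineage regulators, tissue regulators, Hox genes, ribosomal proteins, body wall muscle, pharynx, intestine, cuticle collagens, epidermal junctions and elongation, apical matrix and cuticle enzymes, synaptic and neuronal function, neuropeptides, ciliated neuron transport, programmed cell death, heat shock and stress response, mitochondrially encoded genes, adult yolk proteins and sperm, and 13 of their names matched no gene of the table. In 4 of the 108 tests the median, the mean and the test differed in sign, and none of the 4 was called. No called list changed direction with relative log expression size factors.

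Profiles of log2 CPM with a pseudocount of 10 CPM over 9923 genes were compared by Pearson correlation, and 1 minus the correlation was related to the gap in labelled time with 100000 permutations of the time labels. The time of each embryo was predicted with that embryo left out, as the point of a 10 min grid at which profiles smoothed with a Gaussian kernel of 20 min SD had the highest correlation with its own profile. The X-linked share of counts was compared between windows by permutation tests, exact within run 5 where the groups allow. Tables and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

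The edgeR test was tested on simulated data built on the depths and spread of T2 and T3, with 6144 genes: 18 of 100 genes changed 2-fold and 70 of 100 changed 4-fold were called, and 2 of 5944 unchanged genes, which were 2.22% of the calls. The prediction of time was tested on simulated embryos, drawn with counting noise alone from profiles smoothed over all embryos. Of these, 139 of 139 were placed within 20 min. The references came from the same embryos, so this covers counting noise at the real depths and not the spread between embryos or runs. Over all embryos 47.2% of reads were counted in genes. Small changes of genes with few counts are out of reach.

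The runs were read from the order of the labelled times along the title numbers: run 1, numbers 1 to 50, has times in no fixed order, and runs 2 to 5 begin again at an early time and ascend. Alternatives were relative log expression size factors, DESeq2 1.42.0, no low-count filter, no fold threshold, run as a covariate, 1 run only (run 5 up to T6, run 1 for T6 to T7), leaving out libraries with fewer than 230883 gene counts or embryos within 20 min of the boundary, other correlations, kernels and gene sets for the profiles, references from other runs, and other measures of the X share. Added after the data were seen were fits without 4 embryos of run 1, without 3 libraries of run 2, and without the 2 embryos farthest from the median time, and lists within 1 run. No embryo was left out of the results as reported.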

Results

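Messenger RNA was measured in 139 single embryos of the nematode Caenorhabditis elegans by CEL-Seq, a method that tags the RNA of each sample with a barcode, amplifies it by in vitro transcription and sequences the 3′ ends of transcripts. Each embryo carried a time in minutes relative to the 4-cell stage, from -50 to 840 min, and 86 distinct times were present, 21 of them with more than 1 embryo. For the comparisons the embryos were placed in 7 time windows: T1, -50 to 30 min, 17 embryos; T2, 40 to 100 min, 11 embryos; T3, 110 to 190 min, 13 embryos; T4, 200 to 290 min, 30 embryos; T5, 300 to 390 min, 18 embryos; T6, 400 to 590 min, 25 embryos; T7, 600 to 840 min, 25 embryos. Gene counts per embryo ran from 12338 to 4557314 with a median of 692649, and 1287 to 12378 genes were detected in an embryo, with a median of 8316. Median gene counts per embryo were 648258 in T1, 699720 in T2, 1187968 in T3, 394191 in T4, 1496589 in T5, 531473 in T6 and 559134 in T7. The title numbers of the embryos fall into 5 blocks of consecutive numbers, called run 1 to run 5 here, with 50, 20, 12, 12 and 45 embryos, and the labels name no batch. All 25 embryos of T7 and 18 of the 25 embryos of T6 were in run 1, while 10 of the 18 embryos of T5 and 3 of the 25 of T6 were in run 5. The median share of reads that did not align was 56.5% in run 1, 35.0% in run 2, 37.0% in run 3, 34.5% in run 4 and 26.1% in run 5.

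The series asks how the transcriptome changes through embryogenesis at high time resolution. Transcripts loaded by the mother were highest in the earliest window and lineage, tissue and cuticle genes followed in turn. The mRNA of pos-1 (F52E1.1), a maternal RNA-binding protein that specifies posterior fates, had a mean of 6873 ± 3039 CPM (counts scaled to a common total per embryo, SD, n = 17) in T1, 1702 ± 1419 CPM in T2 and 487 ± 614 CPM in T3. The P granule gene pgl-1 went from 389 ± 191 CPM in T1 to 27.7 ± 28.7 CPM in T4. The endoderm gene end-1 was at 46.1 ± 33.1 CPM in T2 and 42.6 ± 30.5 CPM in T3, and no count of it was found in the 25 embryos of T6 or the 25 of T7. Transcripts of med-1, which acts upstream of end-1, were at 4.58 ± 7.53 CPM in T1 with counts in 6 of 17 embryos, and end-3 was at 11.2 ± 17.4 CPM in T2 with counts in 6 of 11. These 2 genes had too few counts to be tested across windows. The intestinal regulator elt-2 was highest in T4 at 51.3 ± 29.7 CPM, as were the pharyngeal regulator pha-4 at 665 ± 244 CPM and the gut esterase ges-1 at 22.9 ± 15.1 CPM. The muscle regulator hlh-1 was at 71.3 ± 56.8 CPM in T3 and 63.2 ± 43.3 CPM in T4, where 4 embryos of run 1 that resemble later embryos had 0 to 9.99 CPM. The epidermal regulator elt-1 had its highest mean in T3, 324 ± 123 CPM, while the epidermal gene lin-26 was at 207 ± 96.0 CPM in T1, 47.4 ± 38.8 CPM in T2 and 318 ± 139 CPM in T5. The ribonucleotide reductase gene rnr-1 went from 778 ± 546 CPM in T1 to 28.7 ± 31.5 CPM in T7.

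Genes of differentiated cells were highest later. The collagen sqt-3 was at 51.3 ± 82.0 CPM in T2 and 7548 ± 2455 CPM in T6, and the collagen dpy-7 was at 1129 ± 826 CPM in T6 and 10.9 ± 20.2 CPM in T7. The cilium gene osm-6 was highest in T6, 17.3 ± 15.4 CPM. Body wall muscle myosin unc-54 went from 28.1 ± 43.8 CPM in T1 to 1361 ± 618 CPM in T7, and pharyngeal myosin myo-2 from 3.89 ± 5.65 CPM in T5 to 439.5 ± 283 CPM in T7. The synaptic vesicle gene rab-3 had no counts in the 17 embryos of T1 and reached 256 ± 125 CPM in T7. The locus that holds the acetylcholine genes cha-1 and unc-17 (ZC416.8, 1 count for both) was at 0.198 ± 0.839 CPM in T5 and 61.2 ± 37.5 CPM in T7. The yolk gene vit-2, expressed in the adult intestine, was found in every window, between 396 ± 717 CPM in T1 and 1725 ± 1854 CPM in T7. All 18 of these genes that could be tested differed among windows (edgeR, largest adjusted p = 1.2e-05 for vit-2). Over all genes, 9304 of 9923 tested differed among the 7 windows at an adjusted p under 0.05, which is 93.8%.

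**Figure D1:**
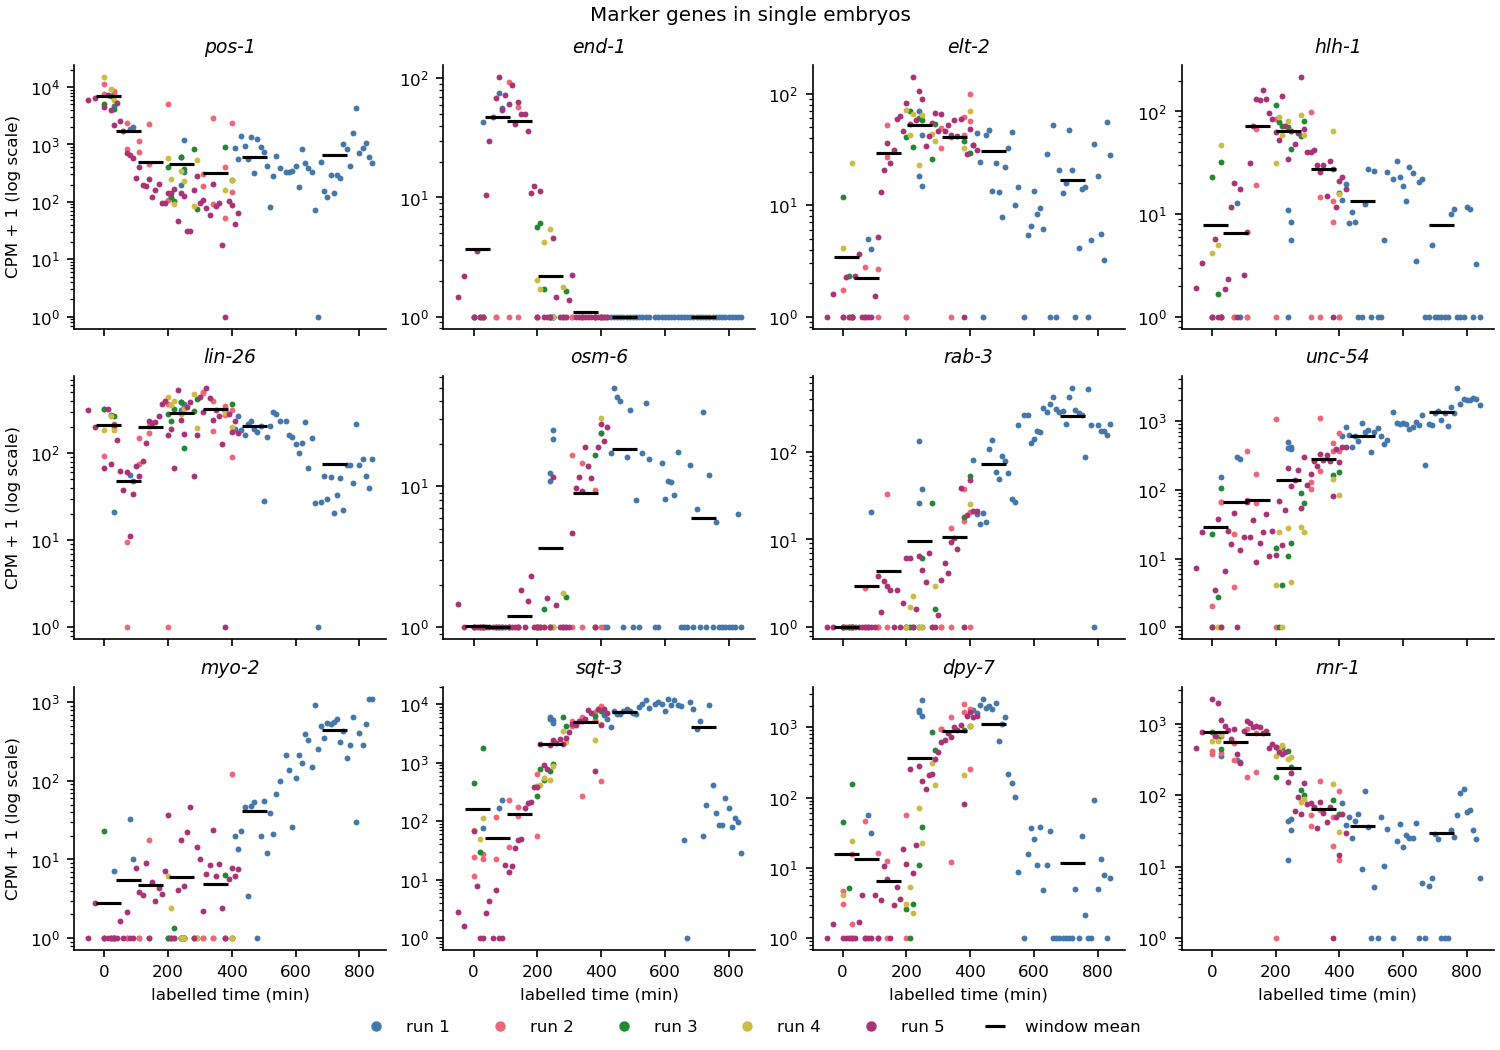
CPM plus 1 on a log scale for 12 marker genes in 139 embryos against labelled time in minutes, with 1 point per embryo coloured by run and a black bar at the mean of each window. The maternal gene pos-1 is highest in T1, end-1 has no counts in T6 and T7, and myo-2 is highest in T7.

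Embryos labelled close in time had more similar transcriptomes than embryos labelled far apart. Same-time pairs had a mean correlation of log2 CPM profiles of 0.766 ± 0.149 (SD, 109 pairs, 97 across runs). It was 0.820 ± 0.132 at 10 to 20 min apart (470, 278 across runs) and 0.784 ± 0.130 at 30 to 60 min (928). At 250 to 890 min it was 0.414 ± 0.125 (4525). The bins also differ in embryos and runs, not in age alone. The distance between profiles (1 minus the correlation) rose with the gap in labelled time over 9591 pairs, with Pearson r = 0.804 and Spearman rho = 0.834. Both permutation p-values were 1e-05, the smallest that 100000 two-sided permutations of the time labels can give. Without the 2 embryos farthest from the median time, r was 0.808 and rho 0.836. Within runs 1 to 5 the Pearson r was 0.684, 0.569, 0.811, 0.971 and 0.877 and the Spearman rho 0.722, 0.541, 0.808, 0.952 and 0.873, each with p = 1e-05 and Benjamini-Hochberg p over the 5 runs = 1e-05. Over pairs from different runs r was 0.813.

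When the time of each embryo was predicted from the profiles of the other embryos, the median absolute error was 10 min, with quartiles of 5 and 30 min. The prediction lay within 20 min of the label for 103 of 139 embryos and within 30 min for 119. It missed by more than 100 min in 7 embryos. Of these, 4 were embryos of run 1 labelled 240, 240, 250 and 250 min and predicted at 420, 420, 430 and 430 min. The other 3 were libraries of run 2 labelled 200, 340 and 400 min, predicted at 790, 790 and 800 min. Their best correlations were 0.459, 0.566 and 0.544. With references from other runs only, the median error over 100 embryos was 20 min. Those 7 embryos stay in T4, T5 and T6 by their labels, and the comparisons of T4 give the counts of genes without the 4 embryos. Without the 3 libraries every count of genes called stayed within 1.5 times, with 738 higher and 539 lower from T4 to T5, 1345 and 746 from T5 to T6, and 702 and 910 from T6 to T7.

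**Figure D2:**
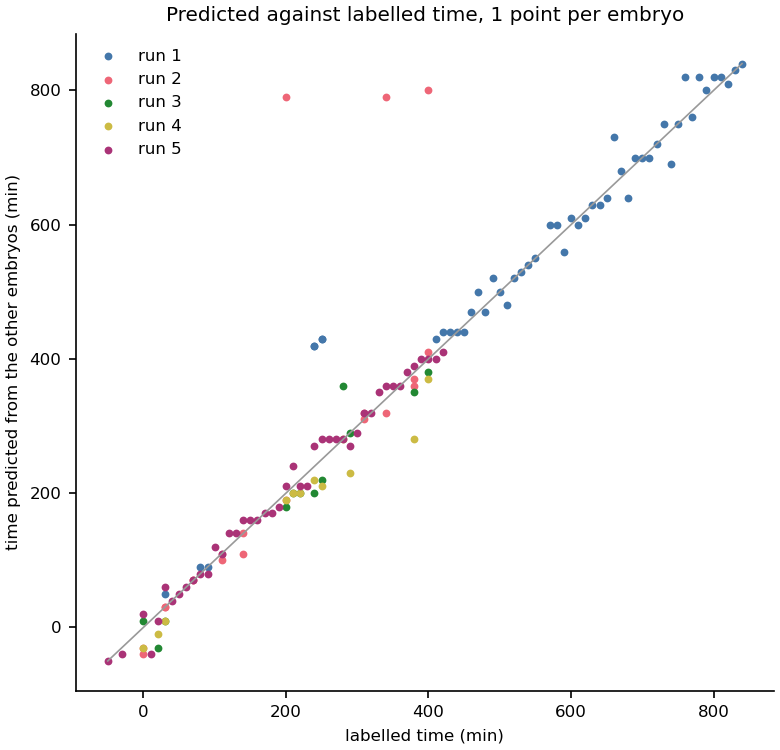
Time predicted from the other embryos against labelled time, both in minutes, with 1 point per embryo coloured by run and a grey line of equality. Of 139 embryos 103 lie within 20 min of the label, 4 embryos of run 1 labelled 240 or 250 min lie at 420 or 430 min and 3 libraries of run 2 lie at 790 or 800 min.

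The comparison of T1 with T2 covers the time from before the 4-cell stage to gastrulation and asks which maternal transcripts disappear and which embryonic ones appear. Of the maternal regulators 23 of 35 fell and 2 rose, while 16 of 19 early zygotic lineage regulators and 72 of 76 ribosomal protein genes rose. The homeobox gene ceh-51 (Y80D3A.3, chromosome V), which acts in the mesoderm lineage, rose from 6.12 ± 24.2 to 120.2 ± 89.2 CPM (SD, n = 17 and 11; log2 fold change 7.38 ± 0.77 (SE), adjusted p = 5.18e-08). The F-box genes fbxb-38, fbxb-108, fbxb-19 and fbxb-90, whose family links proteins to ubiquitin ligases, rose with log2 fold changes of 6.62 to 7.51, with fbxb-90 going from 11.7 ± 28.3 to 162 ± 133 CPM. The uncharacterised gene F34D6.1 rose by 6.86 on the log2 scale. Among the largest falls were marc-3 (C17E4.3, chromosome I), a RING-type ubiquitin ligase gene, from 169 ± 175 to 11.6 ± 15.6 CPM, memi-1, which acts in oocyte meiosis, from 59.5 ± 47.3 to 6.28 ± 9.56 CPM, and neg-1, a maternal gene of anterior fate, from 178 ± 214 to 15.3 ± 18.1 CPM (log2 fold changes -3.35, -2.90 and -2.98). T21C9.13, F15D3.6 and ltah-1.1 fell with log2 fold changes of -3.01, -2.91 and -3.05. The 12 genes with the largest rises and falls had adjusted p from 5.18e-08 to 0.00119.

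Of 35 maternal oocyte-to-embryo regulators, 2 rose (par-2 and perm-4), 23 fell and 10 were not called, and 3 rose and 23 fell adjusted over the list alone. The maternal list had adjusted p = 9.08e-08 and adjusted p = 0.322 with an estimated correlation. Examples were zif-1, the adaptor that targets maternal zinc-finger proteins for destruction, which fell from 542 ± 246 to 77.7 ± 78.8 CPM, and the oocyte maturation gene oma-2, which fell from 1565 ± 1352 to 221 ± 143 CPM. Among 25 germline P granule and small RNA factors, 0 rose, 12 fell and 13 were not called, and 0 rose and 12 fell adjusted over the list alone. The P granule list had adjusted p = 0.00199 and adjusted p = 0.490 with an estimated correlation. The P granule genes meg-1 and pgl-3 fell with log2 fold changes of -2.17 and -2.04. Of 19 early zygotic lineage regulators, 16 rose, 0 fell and 3 were not called, and 18 rose and 0 fell adjusted over the list alone. The early zygotic list had adjusted p = 3.26e-10 and adjusted p = 0.223 with an estimated correlation. Besides ceh-51, sdz-26, a gene that depends on the maternal regulator SKN-1, rose from 8.15 ± 21.1 to 125 ± 78.9 CPM. Among 76 ribosomal protein genes, 72 rose, 0 fell and 4 were not called, and 72 rose and 0 fell adjusted over the list alone. The ribosomal list had adjusted p = 1.24e-19 and adjusted p = 0.473 with an estimated correlation. The examples rpl-14 and rps-15 had log2 fold changes of 1.97 and 1.95. Of 12 mitochondrially encoded genes, 10 rose, 0 fell and 2 were not called, and 10 rose and 0 fell adjusted over the list alone. The mitochondrial list had adjusted p = 9.25e-05 and adjusted p = 0.490 with an estimated correlation. The NADH dehydrogenase gene ND1 rose from 804 ± 478 to 1739.6 ± 1635 CPM and MTCE.25 from 172 ± 68.7 to 393 ± 200.5 CPM. Among 56 DNA replication and mitosis genes, 3 rose (rpa-2, spd-1 and top-2), 3 fell (cyb-2.1, cyb-2.2 and orc-1) and 50 were not called, and 4 rose and 3 fell adjusted over the list alone. The replication list had a median log2 fold change of 0.54, adjusted p = 0.0110 and adjusted p = 0.490 with an estimated correlation. Of 22 cuticle collagen genes, 12 rose, 0 fell and 10 were not called, and 17 rose and 0 fell adjusted over the list alone. The collagen list had adjusted p = 0.00517 and adjusted p = 0.681 with an estimated correlation. The collagens col-20 and col-160 rose by 2.94 and 2.40 on the log2 scale, but within run 5 (6 and 7 embryos) their log2 fold changes were 0.48 and 0.56 and neither was called, nor was the collagen list (median 0.64). Over the 11 embryos of T2, transcripts of adult yolk protein genes took 0.599 ± 0.779% of counts, with 1.95 ± 0.433% in 2 embryos of run 1, 1.03 ± 0.0976% in 2 of run 2 and 0.0885 ± 0.0567% in 7 of run 5. Over embryos of T1 to T3, with the mean of each run and window subtracted, the Pearson r with that share was 0.87 for perm-4, 0.81 for col-20 and 0.91 for col-160.

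In all, 852 of 5636 genes tested were higher in T2 and 817 lower, at an adjusted p under 0.05 and a fold of at least 2. Within run 5 the counts were 860 and 749, memi-1 had too few counts to be tested, the maternal and early zygotic lists stayed past their thresholds, and the heat shock list passed there (median -0.63, adjusted p = 0.0283) but not over all runs. Log2 fold changes of named genes that differed there by more than 1.5 times as folds were 6.31 for fbxb-38, 6.29 for ceh-51, 5.78 for fbxb-108, 5.67 for fbxb-19, -4.52 for marc-3, -3.65 for ltah-1.1, -3.61 for T21C9.13, -5.20 for neg-1, 1.17 for rps-15, 6.70 for sdz-26, -3.13 for oma-2 and -2.99 for pgl-3. With run as a covariate they were 6.30 for fbxb-108, 5.99 for fbxb-90, -3.77 for ltah-1.1, -3.77 for neg-1, 1.65 for col-20 and 1.17 for col-160, and col-20 lost its call. The p-values of this and the later comparisons measure the spread between embryos of a window, which also differ in age.

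From T2 to T3, when cell division continues and tissue fates are set, 12 of 20 tissue regulators and 6 of 23 epidermal junction genes rose, while 11 of 34 maternal regulators and 8 of 19 P granule and small RNA genes fell. The leucine zipper gene zip-8 (F23F12.9, chromosome III) rose to 1372 ± 1222 CPM in T3 (SD, n = 13; log2 fold change 6.35 ± 0.84 (SE), adjusted p = 3.7e-06). The muscle regulator unc-120 rose from 8.27 ± 12.1 to 179 ± 113 CPM (SD, n = 11 and 13), the neural regulator sox-2 from 5.75 ± 5.27 to 148 ± 260.1 CPM, the zinc-finger gene somi-1 from 3.67 ± 4.60 to 220.3 ± 276 CPM, and sym-1, which acts in muscle attachment to the epidermis, from 7.49 ± 15.2 to 223 ± 318 CPM. C06B8.7 rose by 4.38 on the log2 scale. The cell cycle phosphatase gene cdc-25.3 (ZK637.11, chromosome III) fell from 541 ± 633 to 9.08 ± 14.3 CPM (log2 fold change -6.16 ± 0.78 (SE), adjusted p = 1.81e-06). The genes Y5H2B.3, D1086.19, C05D12.4, sgnh-1 and Y38E10A.3 fell with log2 fold changes of -7.76 to -6.38, and Y5H2B.3 fell from 250.0 ± 188 to 1.11 ± 1.17 CPM. The 12 genes had adjusted p from 5.59e-10 to 7.12e-04.

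Among 20 tissue regulators, 12 rose, 1 fell (hlh-3) and 7 were not called, and 15 rose and 1 fell adjusted over the list alone. The tissue regulator list had adjusted p = 2.95e-06 and adjusted p = 0.266 with an estimated correlation. Next to unc-120, the homeobox gene ceh-27 rose from 9.53 ± 20.7 to 175 ± 87.2 CPM. Of 23 epidermal junction and elongation genes, 6 rose, 0 fell and 17 were not called, and 6 rose and 0 fell adjusted over the list alone. The epidermal list had a median log2 fold change of 0.76, adjusted p = 0.0133 and adjusted p = 0.490 with an estimated correlation. The junction gene dlg-1 rose from 8.04 ± 5.39 to 89.3 ± 122 CPM and the ephrin gene efn-4 from 15.9 ± 18.0 to 128 ± 115 CPM. Among 34 maternal regulators, 0 rose, 11 fell and 23 were not called, and 0 rose and 12 fell adjusted over the list alone. The maternal list had a median log2 fold change of -1.01, adjusted p = 1.56e-04 and adjusted p = 0.496 with an estimated correlation. The falls included oma-1, from 339.6 ± 139.8 to 48.4 ± 54.4 CPM, and gld-3, which acts in polyadenylation of maternal mRNA, from 153 ± 185 to 20.2 ± 17.6 CPM. Of 19 P granule and small RNA genes, 0 rose, 8 fell and 11 were not called, and 0 rose and 9 fell adjusted over the list alone. The P granule list had adjusted p = 5.46e-04 and adjusted p = 0.490 with an estimated correlation. The Argonaute gene csr-1 and ekl-1, of the same small RNA pathway, fell with log2 fold changes of -2.67 and -2.14. Among 76 ribosomal protein genes, 3 rose (rpl-11.2, rpl-25.1 and rps-22), 0 fell and 73 were not called, and 0 rose and 0 fell adjusted over the list alone. The ribosomal list had a median log2 fold change of 0.19, adjusted p = 0.00751 and adjusted p = 0.766 with an estimated correlation. The X-linked paralogs rpl-11.2 and rpl-25.1 were 2 of the 3, with log2 fold changes of 1.23 and 1.19. Of 18 programmed cell death genes, 3 rose (ced-4, crn-6 and nuc-1), 1 fell (crn-3) and 14 were not called, and 3 rose and 1 fell adjusted over the list alone. The cell death list had a median log2 fold change of 0.17, adjusted p = 0.242 and adjusted p = 0.673 with an estimated correlation. The 3 that rose included the nucleases of DNA degradation nuc-1, from 19.7 ± 23.9 to 105 ± 53.0 CPM, and crn-6, from 34.2 ± 28.7 to 155 ± 61.6 CPM, and the list itself did not pass its test.

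In all, 639 of 6144 genes tested were higher in T3 and 869 lower. Median-based size factors moved the median log2 fold change of all genes up by 0.12, and with DESeq2 the split was 951 higher and 818 lower. Within run 5 (7 and 9 embryos) 1307 genes were higher and 1323 lower and 8 lists were called against 5 over all runs, the others being body wall muscle (median 0.62), intestine (0.61) and mitochondrially encoded genes (-0.93), and without the embryos within 20 min of the boundary 1024 were higher. Named genes that moved by more than 1.5 times as folds within run 5 had log2 fold changes of 6.83 for sym-1, 5.34 for unc-120, -7.60 for Y38E10A.3, -3.72 for gld-3, 2.22 for rpl-25.1 and 1.91 for efn-4, rpl-11.2 also rose more there, and with run as a covariate the values were 6.62 for sym-1, 5.13 for unc-120 and 1.85 for rpl-25.1.

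From T3 to T4, 17 of 21 apical matrix genes, 15 of 29 epidermal genes and 21 of 37 muscle genes rose, while 9 of 12 early zygotic regulators and 20 of 55 replication genes fell. The POU homeobox gene unc-86 (C30A5.7, chromosome III), which specifies neurons, rose from 0.306 ± 0.423 to 56.4 ± 60.6 CPM (SD, n = 13 and 30; log2 fold change 6.91 ± 0.99 (SE), adjusted p = 3.13e-07). The leucine zipper gene ces-2, which acts in the choice of cell death, rose from 5.02 ± 10.1 to 616 ± 844 CPM and the small heat shock gene hsp-12.1 from 0.522 ± 0.905 to 107 ± 150.0 CPM. The intermediate filament gene ifa-3, the LIM homeobox gene lin-11 and the lipocalin gene lpr-4 were also among the 6 largest rises, with log2 fold changes of 7.29, 6.75 and 6.72. The very early transcript vet-1 (T05E7.5, chromosome I) fell from 2402 ± 3936 to 15.6 ± 39.9 CPM (log2 fold change -7.72 ± 0.77 (SE), adjusted p = 5.78e-11), the autophagy adaptor gene sepa-1 from 664 ± 588 to 7.08 ± 11.0 CPM and the Skp1-related gene skr-15 from 462 ± 395 to 6.26 ± 12.8 CPM. F56G4.2 and F56G4.3, neighbours on chromosome I, and the gene sdz-30 fell with log2 fold changes of -6.89 to -6.26. The 12 genes had adjusted p from 2.59e-14 to 1.32e-04.

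Among 55 DNA replication and mitosis genes, 0 rose, 20 fell and 35 were not called, and 0 rose and 20 fell adjusted over the list alone. The replication list had adjusted p = 2.07e-12 and adjusted p = 0.415 with an estimated correlation. The replication clamp gene pcn-1 fell from 1642 ± 538 to 396 ± 284 CPM and the helicase gene mcm-2 from 443 ± 198 to 127 ± 118 CPM. Of 12 early zygotic lineage regulators, 0 rose, 9 fell and 3 were not called, and 0 rose and 9 fell adjusted over the list alone. The early zygotic list had adjusted p = 1.75e-09 and adjusted p = 0.160 with an estimated correlation. Among 21 apical matrix and cuticle enzyme genes, 17 rose, 0 fell and 4 were not called, and 17 rose and 0 fell adjusted over the list alone. The apical matrix list had adjusted p = 1.1e-11 and adjusted p = 0.220 with an estimated correlation. The moulting gene mlt-8 rose from 10.9 ± 29.5 to 419.9 ± 879 CPM and dyf-7, which anchors dendrite tips, from 2.08 ± 4.51 to 41.7 ± 48.6 CPM. Of 37 body wall muscle contractile genes, 21 rose, 0 fell and 16 were not called, and 24 rose and 0 fell adjusted over the list alone. The muscle list had adjusted p = 3.56e-05 and adjusted p = 0.593 with an estimated correlation. Troponin I gene tni-1 rose from 6.80 ± 6.94 to 249 ± 442 CPM and the tropomodulin gene tmd-2 by 6.68 on the log2 scale. Among 29 epidermal junction and elongation genes, 15 rose, 1 fell (efn-4) and 13 were not called, and 15 rose and 1 fell adjusted over the list alone. The epidermal list had adjusted p = 1.13e-04 and adjusted p = 0.490 with an estimated correlation. The RhoGAP gene rga-2, needed for elongation, rose from 2.21 ± 3.37 to 96.8 ± 195 CPM. Of 32 tissue regulators, 13 rose, 1 fell (elt-1) and 18 were not called, and 13 rose and 2 fell adjusted over the list alone. The tissue regulator list had adjusted p = 0.00876 and adjusted p = 0.528 with an estimated correlation. Among 6 ciliated neuron transport genes, 4 rose (dli-1, dyf-11, klp-11 and klp-20), 0 fell and 2 were not called, and 4 rose and 0 fell adjusted over the list alone. The cilium list had adjusted p = 0.0133 and adjusted p = 0.477 with an estimated correlation. Of 76 ribosomal protein genes, 5 rose (rpl-11.2, rpl-26, rpl-36, rpl-37 and rps-1), 1 fell (rpl-11.1) and 70 were not called, and 5 rose and 1 fell adjusted over the list alone. The ribosomal list had a median log2 fold change of 0.52, adjusted p = 5.62e-04 and adjusted p = 0.704 with an estimated correlation. Of the paralogs of ribosomal protein L11, rpl-11.2 rose from 426 ± 204 to 1156 ± 468 CPM and rpl-11.1 fell from 425 ± 398 to 204 ± 280.3 CPM. Among 5 Hox genes, 2 rose (lin-39 and mab-5), 0 fell and 3 were not called, and 2 rose and 0 fell adjusted over the list alone. The Hox list had adjusted p = 0.244 and adjusted p = 0.590 with an estimated correlation.

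In all, 855 of 6281 genes tested were higher in T4 and 510 lower, with 663 and 629 when the 4 embryos of run 1 labelled 240 or 250 min were left out. The genes lpr-4, ifa-3, lin-11 and tmd-2 then had too few counts to be tested, since the other 26 embryos of T4 had 21.9 ± 44.9, 55.2 ± 90.2, 33.8 ± 43.1 and 16.3 ± 22.4 CPM. Without the 4 embryos the log2 fold changes of mlt-8, tni-1, rga-2, hsp-12.1 and unc-86 were 3.72, 3.61, 3.74, 6.32 and 6.17, against 5.51, 5.45, 5.40, 7.39 and 6.91 with them, and that of vet-1 was -8.95. The medians of the muscle, epidermal and ribosomal lists were then 0.86, 0.59 and 0.23, against 1.63, 1.10 and 0.52, the ribosomal list lost its call, and the maternal and yolk lists gained one (medians -0.99 and -2.52, adjusted p = 0.0138 and 0.0363). The run-5 embryos of T4 labelled 200, 210, 220, 240, 280 and 290 min were shallow, with 18624 to 194089 gene counts. Within run 5 (9 and 10 embryos) 760 genes were higher and 743 lower. There the lists of tissue regulators and of cilium transport lost their calls (medians 0.18 and 0.73), and the collagen and intestinal lists gained one (medians 1.45 and 0.95 against 0.44 and 0.48, adjusted p = 3.09e-07 and 0.00104). Among the named genes the log2 fold changes that moved by more than 1.5 times as folds were 6.26 for hsp-12.1, 8.08 for ces-2, -10.21 for vet-1, -9.08 for sepa-1, -7.36 for F56G4.3, -8.95 for sdz-30, -8.67 for skr-15, 5.09 for dyf-7, 4.50 for tni-1 and 3.55 for rga-2 within run 5, and 6.16 for hsp-12.1, 6.23 for ifa-3, 6.08 for unc-86, 6.02 for lin-11, 3.08 for lpr-4, -8.79 for vet-1, -7.58 for sepa-1, -7.42 for F56G4.3, -9.06 for sdz-30, -6.97 for skr-15, 4.50 for mlt-8, 4.40 for tmd-2, 3.83 for tni-1 and 4.22 for rga-2 with run as a covariate. Without the embryos within 20 min of the boundary 767 genes were lower.

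From T4 to T5, as the embryo elongates, 40 of 53 replication genes fell, and 15 of 38 muscle genes, 4 of 31 epidermal genes and 6 of 24 apical matrix genes rose. The helicase gene mcm-7 (F32D1.10, chromosome V) fell from 917 ± 687 to 129 ± 113 CPM (SD, n = 30 and 18; log2 fold change -2.76 ± 0.45 (SE), adjusted p = 2.37e-05), and the replication licensing gene cdt-1 from 412 ± 295 to 90.2 ± 75.4 CPM. The chitinase gene cht-1 fell from 2094 ± 1804 to 74.1 ± 146 CPM, the Skp1-related gene skr-7 from 269 ± 358 to 6.28 ± 5.46 CPM and jmjd-3.2, of a histone demethylase family, from 78.5 ± 68.0 to 2.81 ± 7.65 CPM. The leucine zipper gene zip-7 fell from 128 ± 151 to 0.459 ± 1.02 CPM, and B0281.5 and Y82E9BR.17 fell with log2 fold changes of -4.88 and -4.72. Among the largest rises were zig-4, which keeps axons in place, by 2.69 on the log2 scale, the lipocalin gene lpr-7 from 6.60 ± 13.9 to 63.0 ± 74.2 CPM, the sterol methyltransferase gene strm-1 from 11.6 ± 25.9 to 75.5 ± 82.2 CPM and hot-6 from 10.0 ± 19.1 to 51.5 ± 50.1 CPM. The uncharacterised genes R03A10.5 (chromosome X) and C44E12.1 rose by 3.31 and 2.99 on the log2 scale. The 12 genes of the largest changes had adjusted p from 8.29e-08 to 0.00390.

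Of 53 DNA replication and mitosis genes, 0 rose, 40 fell and 13 were not called, and 0 rose and 40 fell adjusted over the list alone. The replication list had adjusted p = 1.1e-22 and adjusted p = 0.223 with an estimated correlation. Among 7 early zygotic lineage regulators, 0 rose, 4 fell (hnd-1, tbx-11, tbx-8 and tbx-9) and 3 were not called, and 0 rose and 4 fell adjusted over the list alone. The early zygotic list had adjusted p = 0.00228 and adjusted p = 0.266 with an estimated correlation. Of 38 body wall muscle contractile genes, 15 rose, 0 fell and 23 were not called, and 18 rose and 0 fell adjusted over the list alone. The muscle list had adjusted p = 8.42e-12 and adjusted p = 0.415 with an estimated correlation. The troponin C gene pat-10 rose from 291 ± 321 to 1201 ± 516 CPM and the perlecan gene unc-52 from 73.9 ± 97.1 to 265 ± 163 CPM. Among 31 epidermal junction and elongation genes, 4 rose (fhod-1, ifa-3, let-805 and mup-4), 0 fell and 27 were not called, and 4 rose and 0 fell adjusted over the list alone. The epidermal list had a median log2 fold change of 0.69, adjusted p = 4.71e-05 and adjusted p = 0.496 with an estimated correlation. The formin gene fhod-1 rose from 42.7 ± 53.7 to 171 ± 120.2 CPM and ifa-3 from 93.0 ± 134 to 375 ± 228 CPM. Of 42 cuticle collagen genes, 7 rose, 2 fell (col-111 and col-129) and 33 were not called, and 7 rose and 1 fell adjusted over the list alone. The collagen list had a median log2 fold change of 0.32, adjusted p = 5.32e-04 and adjusted p = 0.673 with an estimated correlation. The collagens col-76 and dpy-3 rose by 1.90 and 1.78 on the log2 scale. Among 24 apical matrix and cuticle enzyme genes, 6 rose, 0 fell and 18 were not called, and 7 rose and 0 fell adjusted over the list alone. The apical matrix list had a median log2 fold change of 0.80, adjusted p = 5.62e-04 and adjusted p = 0.496 with an estimated correlation. dyf-7 rose from 41.7 ± 48.6 to 194 ± 145 CPM and the hedgehog-related gene wrt-5 from 57.9 ± 49.0 to 191 ± 104 CPM.

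Of 23 synaptic and neuronal genes, 5 rose (aex-3, mec-12, ric-3, sbt-1 and unc-57), 0 fell and 18 were not called, and 5 rose and 0 fell adjusted over the list alone. The neuronal list had a median log2 fold change of 0.59, adjusted p = 0.00363 and adjusted p = 0.496 with an estimated correlation. Among 11 cilium transport genes, 3 rose (che-14, daf-10 and nphp-1), 0 fell and 8 were not called, and 3 rose and 0 fell adjusted over the list alone. The cilium list had a median log2 fold change of 0.79, adjusted p = 0.00529 and adjusted p = 0.496 with an estimated correlation. Of 24 intestinal genes, 2 rose (lbp-6 and nhx-2), 1 fell (elt-7) and 21 were not called, and 2 rose and 1 fell adjusted over the list alone. The intestinal list had a median log2 fold change of 0.59, adjusted p = 0.0333 and adjusted p = 0.593 with an estimated correlation. Among 6 adult yolk protein genes, 0 rose, 0 fell and 6 were not called, and 0 rose and 0 fell adjusted over the list alone. The yolk list had a median log2 fold change of 0.84, adjusted p = 0.0192 and adjusted p = 0.593 with an estimated correlation. Of 76 ribosomal protein genes, 1 rose (rps-22), 0 fell and 75 were not called, and 1 rose and 0 fell adjusted over the list alone. The ribosomal list had a median log2 fold change of 0.60, adjusted p = 1.44e-13 and adjusted p = 0.490 with an estimated correlation. The level of rps-22 went from 613 ± 372 to 1255 ± 589 CPM. In all, 588 of 6684 genes tested were higher in T5 and 492 lower. Without the 4 embryos of run 1 the counts were 1127 and 619 and within run 5 (10 and 10 embryos) 1072 and 617, while run as a covariate gave 1138 and 459 and DESeq2 657 and 761. Without the 4 embryos the medians of the collagen, intestinal, yolk and muscle lists were 1.31, 1.49, 2.22 and 2.27, against 0.32, 0.59, 0.84 and 1.07 with them. The log2 fold changes of lpr-7, strm-1, hot-6, unc-52, ifa-3 and dpy-3 were then 4.89, 4.22, 3.73, 2.99, 2.92 and 2.83, and those of C44E12.1, zig-4, pat-10, fhod-1 and col-76 also lay more than 1.5 times higher as folds. Median-based size factors moved the median log2 fold change of all genes by -0.15, and within run 5 the collagen list lost its call (median 0.17) and zip-7, jmjd-3.2 and B0281.5 had too few counts to be tested. The log2 fold changes of named genes that moved by more than 1.5 times as folds were 3.60 for C44E12.1, 5.05 for lpr-7, 4.72 for strm-1, 3.58 for hot-6, 2.62 for unc-52, 3.13 for fhod-1, 2.90 for ifa-3 and 2.41 for dpy-3 within run 5, and 4.64 for lpr-7, 4.40 for strm-1, 3.39 for hot-6, -6.05 for B0281.5, 2.97 for unc-52, 3.19 for fhod-1, 3.34 for ifa-3, 2.67 for col-76 and 2.64 for dpy-3 with run as a covariate.

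From T5 to T6, where most embryos of the 2 windows came from different runs, 43 of 60 collagens, 21 of 40 muscle genes, 17 of 31 intestinal genes and 17 of 34 neuronal genes rose over all runs. Another 19 of 53 replication genes and 10 of 32 tissue regulators fell, and the collagens as a list had a median of the opposite sign within run 5, whose 3 embryos of T6 are labelled 400 to 420 min. The collagen col-165 (F14H12.1, chromosome X) rose to 5024 ± 10828 CPM in T6 (SD, n = 25; log2 fold change 12.81 ± 1.63 (SE), adjusted p = 2.34e-08). The cuticlin gene cut-3 rose from 1.42 ± 2.47 to 1284 ± 2253 CPM (SD, n = 18 and 25), the hedgehog-related gene wrt-1 from 0.820 ± 1.75 to 445 ± 562 CPM, and the uncharacterised genes F41F3.3 and F33D4.6 from 2.33 ± 2.78 to 2006 ± 2804 CPM and from 1.43 ± 2.66 to 610.0 ± 949 CPM. F15H10.8 had 2 counts over T5 and 1153 over T6, a ratio of pooled counts of 877 with a 95% counting interval of 242 to 7252. The leucine zipper gene ces-2 fell from 756 ± 834 to 30.7 ± 133 CPM, the cuticlin-like gene cutl-2 from 509 ± 454 to 20.8 ± 84.3 CPM, the chondroitin proteoglycan gene cpg-20 from 149 ± 114 to 7.29 ± 17.5 CPM and zig-4 from 141 ± 142 to 7.33 ± 14.2 CPM. The zinc-finger gene M03D4.4 and the Notch ligand gene dsl-3 fell with log2 fold changes of -4.27 and -3.68. The 12 genes had adjusted p from 9.85e-11 to 5.46e-06.

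Among 60 cuticle collagen genes, 43 rose, 0 fell and 17 were not called, and 46 rose and 0 fell adjusted over the list alone. The collagen list had adjusted p = 1.74e-11 and adjusted p = 0.377 with an estimated correlation. One more of them was col-138, from 8.77 ± 34.4 to 71.3 ± 64.6 CPM. Of 40 body wall muscle contractile genes, 21 rose, 0 fell and 19 were not called, and 21 rose and 0 fell adjusted over the list alone. The muscle list had adjusted p = 5.14e-09 and adjusted p = 0.346 with an estimated correlation. The thin filament gene unc-87 rose from 111 ± 156 to 623 ± 374 CPM and the twitchin gene unc-22 from 14.4 ± 18.9 to 54.2 ± 40.9 CPM. Among 31 intestinal genes, 17 rose, 0 fell and 14 were not called, and 18 rose and 0 fell adjusted over the list alone. The intestinal list had adjusted p = 1.29e-07 and adjusted p = 0.204 with an estimated correlation. The examples were dod-6, from 25.7 ± 24.8 to 508 ± 407 CPM, and the intermediate filament gene ifd-1, from 17.7 ± 19.8 to 268 ± 271 CPM. Of 34 synaptic and neuronal genes, 17 rose, 1 fell (unc-119) and 16 were not called, and 19 rose and 1 fell adjusted over the list alone. The neuronal list had adjusted p = 8.05e-07 and adjusted p = 0.266 with an estimated correlation. unc-13, which primes synaptic vesicles, rose from 5.60 ± 7.70 to 76.4 ± 67.4 CPM, and egl-21, which processes neuropeptides, from 10.6 ± 11.6 to 131 ± 86.1 CPM. Among 21 neuropeptide genes, 12 rose, 1 fell (nlp-31) and 8 were not called, and 14 rose and 2 fell adjusted over the list alone. The neuropeptide list had adjusted p = 1.04e-05 and adjusted p = 0.168 with an estimated correlation. The insulin-like gene ins-1 rose from 1.18 ± 3.39 to 41.5 ± 42.9 CPM and nlp-8 from 1.72 ± 2.25 to 53.5 ± 60.4 CPM. Of 8 pharyngeal genes, 6 rose, 0 fell and 2 were not called, and 6 rose and 0 fell adjusted over the list alone. The pharyngeal list had adjusted p = 7.75e-04 and adjusted p = 0.322 with an estimated correlation. Among 25 cilium transport genes, 7 rose, 0 fell and 18 were not called, and 7 rose and 0 fell adjusted over the list alone. The cilium list had a median log2 fold change of 0.66, adjusted p = 0.0110 and adjusted p = 0.593 with an estimated correlation.

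Of 53 DNA replication and mitosis genes, 0 rose, 19 fell and 34 were not called, and 0 rose and 19 fell adjusted over the list alone. The replication list had adjusted p = 7.82e-06 and adjusted p = 0.490 with an estimated correlation. Cyclin A gene cya-1 fell from 116 ± 58.2 to 25.7 ± 31.6 CPM and cdt-1 from 90.2 ± 75.4 to 17.9 ± 26.3 CPM. Among 32 tissue regulators, 0 rose, 10 fell and 22 were not called, and 0 rose and 10 fell adjusted over the list alone. The tissue regulator list had a median log2 fold change of -0.70, adjusted p = 8.26e-04 and adjusted p = 0.518 with an estimated correlation. Of 76 ribosomal protein genes, 1 rose (rps-15), 1 fell (rpl-24.2) and 74 were not called, and 1 rose and 1 fell adjusted over the list alone. The ribosomal list had a median log2 fold change of 0.36, adjusted p = 7.5e-05 and adjusted p = 0.681 with an estimated correlation. Among 34 maternal regulators, 11 rose, 0 fell and 23 were not called, and 11 rose and 0 fell adjusted over the list alone. The maternal list had a median log2 fold change of 0.91, adjusted p = 0.00407 and adjusted p = 0.593 with an estimated correlation. Of 6 adult yolk protein genes, 4 rose (vit-2, vit-4, vit-5 and vit-6), 0 fell and 2 were not called, and 5 rose and 0 fell adjusted over the list alone. The yolk list had adjusted p = 0.0192 and adjusted p = 0.593 with an estimated correlation. Within run 5 the median log2 fold changes of the maternal, yolk and collagen lists were -0.46, -0.44 and -0.67, against 0.91, 1.19 and 1.63 over all runs, and none of the 3 was called, nor was the pharyngeal list (0.17 against 3.27). Those medians differ in age as well as run, since T6 over all runs is labelled 400 to 590 min and in run 5 400 to 420 min. At 410 and 420 min, where both runs held 1 embryo, the maternal gene pos-1 was at 871 and 548 CPM in run 1. In run 5 it was at 40.25 and 63.6 CPM. The yolk gene vit-2 was at 2667 and 4333 CPM in run 1 and at 180 and 486 CPM in run 5. For these genes the runs thus differed at the same labelled age. The epidermal and apical matrix lists were called within run 5 and not over all runs (medians 0.14 and 0.38, adjusted p = 0.0428 and 0.0357). Yolk protein genes took 0.972 ± 0.395% of counts in the 18 embryos of T6 from run 1 and 0.173 ± 0.0652% in the 3 from run 5.

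In all, 1171 of 6941 genes tested were higher in T6 and 639 lower, with 1034 and 943 with relative log expression size factors, which moved the median log2 fold change of all genes by -0.13, and 1113 and 1052 with DESeq2. The 18 embryos of T6 from run 1 are labelled 410 to 590 min and the 7 from other runs 400 to 420 min, and run 1 has none in T5. A fit within run 5 or with run as a covariate therefore sets T5 against the youngest embryos of T6, and it does not separate an effect of run from one of age. With run as a covariate 196 were higher and 19 lower and 218 of the genes called over all runs had the opposite sign, among them cut-3, F33D4.6 and col-138, while within run 5 (10 and 3 embryos) 328 were higher and 158 lower and 239 had the opposite sign. With the covariate 15 of the 23 genes named above were no longer called, and ces-2, cutl-2, M03D4.4, cpg-20, dsl-3, dod-6, ins-1 and F15H10.8 were. Within run 5 col-165, cut-3, F33D4.6, F15H10.8 and col-138 had too few counts to be tested, and zig-4, unc-87, unc-22, ifd-1, unc-13, egl-21, ins-1 and nlp-8 were no longer called. With the covariate the log2 fold changes of the 6 largest rises, col-165, F41F3.3, cut-3, wrt-1, F33D4.6 and F15H10.8, were 1.01, 2.63, -0.53, 2.97, -1.09 and 6.15, against 12.81, 9.90, 9.86, 9.09, 9.03 and 9.02 without it. Those of cya-1 and cdt-1 were -1.83 and -1.96, against -1.83 and -1.82, so their calls were lost with changes about as large, and both stayed called within run 5. For zig-4, col-138, unc-87, unc-22, ifd-1, unc-13, egl-21 and nlp-8 they were -2.57, -0.93, 0.89, 0.80, 1.84, 1.29, 1.34 and 1.14. Of the other genes that kept their call, those that moved by more than 1.5 times as folds had values of -5.71 for ces-2, -6.11 for cutl-2, -3.16 for M03D4.4, -3.43 for cpg-20, -3.01 for dsl-3, 2.53 for dod-6 and 3.73 for ins-1. Without the 3 libraries of run 2 those of col-165 and col-138 were 14.03 and 6.55, against 12.81 and 5.19. Without the embryos within 20 min of the boundary 1260 were higher and 1485 lower.

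From T6 to T7, toward hatching, 46 of 54 neuropeptide genes, 10 of 12 pharyngeal genes and 17 of 33 intestinal genes rose, while 18 of 30 epidermal genes and 19 of 24 apical matrix genes fell. The neuropeptide-like gene nlp-24 (F35B12.7, chromosome V) rose from 93.2 ± 84.1 to 3239.7 ± 3406 CPM (SD, n = 25 and 25; log2 fold change 5.38 ± 0.59 (SE), adjusted p = 8.68e-11) and nlp-29, an epidermal antimicrobial peptide gene, from 19.3 ± 23.9 to 266 ± 333 CPM. The largest rises were those of Y95B8A.2, from 0.895 ± 2.04 to 515 ± 555 CPM, and T14A8.2, from 7.00 ± 13.0 to 1411 ± 1181 CPM, followed by the astacin protease gene nas-30 from 3.58 ± 11.3 to 381 ± 609 CPM, the tyrosinase gene tyr-2 from 10.3 ± 18.2 to 904 ± 1770.5 CPM, the ground-like gene grl-4 from 35.7 ± 35.4 to 2978 ± 3808 CPM and F14D7.12 from 0.751 ± 2.08 to 89.9 ± 77.7 CPM. No count of the collagen col-121 (F56D5.1, chromosome IV) was found in T7. In counts pooled over the embryos of a window, with a floor of 3 counts over the group, it was at least 2580-fold lower than in T6, where its mean over embryos was 382 ± 346 CPM. The epidermal intermediate filament gene ifa-3 had 6083 counts over T6 and 2 over T7, a ratio of pooled counts of 2701 (95% counting interval 747 to 22305). For hch-1, the protease of hatching, the ratio was 1629.8 (95% counting interval 451 to 13462) and for the nuclear receptor gene nhr-43 it was 1020.2 (95% counting interval 183 to 40331). The lipocalin genes lpr-5 and lpr-3 fell from 611 ± 541 to 0.724 ± 1.71 CPM and from 777 ± 797 to 4.16 ± 6.84 CPM. The 12 genes of the largest changes had adjusted p from 2.2e-20 to 1.03e-07.

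Among 54 neuropeptide genes, 46 rose, 0 fell and 8 were not called, and 47 rose and 0 fell adjusted over the list alone. The neuropeptide list had adjusted p = 6.09e-21 and adjusted p = 0.168 with an estimated correlation. Of 12 pharyngeal genes, 10 rose, 0 fell and 2 were not called, and 11 rose and 0 fell adjusted over the list alone. The pharyngeal list had adjusted p = 5.1e-08 and adjusted p = 0.223 with an estimated correlation. The gland gene phat-5 rose from 96.3 ± 176 to 1204 ± 575 CPM and myo-2 from 40.8 ± 51.8 to 439.5 ± 283 CPM. Among 33 intestinal genes, 17 rose, 1 fell (inx-16) and 15 were not called, and 17 rose and 1 fell adjusted over the list alone. The intestinal list had adjusted p = 1.09e-05 and adjusted p = 0.314 with an estimated correlation. The intestinal filament genes ifc-1 and ifc-2 rose from 6.89 ± 10.4 to 189 ± 126 CPM and from 27.2 ± 36.5 to 254 ± 129 CPM. Of 84 cuticle collagen genes, 35 rose, 8 fell and 41 were not called, and 36 rose and 8 fell adjusted over the list alone. The collagen list had adjusted p = 8.75e-11 and adjusted p = 0.309 with an estimated correlation. The collagens that fell included dpy-3, from 226 ± 217 to 1.04 ± 2.80 CPM. Among 24 apical matrix and cuticle enzyme genes, 1 rose (nas-7), 19 fell and 4 were not called, and 1 rose and 19 fell adjusted over the list alone. The apical matrix list had adjusted p = 2.99e-08 and adjusted p = 0.168 with an estimated correlation. Besides lpr-3, wrt-2 fell from 457 ± 503 to 2.66 ± 4.70 CPM. Of 30 epidermal junction and elongation genes, 0 rose, 18 fell and 12 were not called, and 0 rose and 18 fell adjusted over the list alone. The epidermal list had adjusted p = 2.93e-05 and adjusted p = 0.469 with an estimated correlation. The RhoGAP gene rga-2 fell with a log2 fold change of -4.30.

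Among 41 body wall muscle contractile genes, 15 rose, 3 fell (sgca-1, tmd-2 and tnt-3) and 23 were not called, and 15 rose and 3 fell adjusted over the list alone. The muscle list had adjusted p = 6.62e-05 and adjusted p = 0.493 with an estimated correlation. Of 35 synaptic and neuronal genes, 12 rose, 3 fell (syd-2, unc-119 and unc-33) and 20 were not called, and 12 rose and 4 fell adjusted over the list alone. The neuronal list had adjusted p = 0.00366 and adjusted p = 0.496 with an estimated correlation. Among 8 cilium transport genes, 0 rose, 4 fell (che-14, dyf-1, dyf-11 and klp-20) and 4 were not called, and 0 rose and 4 fell adjusted over the list alone. The cilium list had adjusted p = 0.0356 and adjusted p = 0.490 with an estimated correlation. Of 22 tissue regulators, 0 rose, 9 fell and 13 were not called, and 0 rose and 10 fell adjusted over the list alone. The tissue regulator list had adjusted p = 0.00230 and adjusted p = 0.490 with an estimated correlation. Among 76 ribosomal protein genes, 0 rose, 0 fell and 76 were not called, and 0 rose and 0 fell adjusted over the list alone. The ribosomal list had a median log2 fold change of 0.23, adjusted p = 0.00131 and adjusted p = 0.681 with an estimated correlation. Of 14 heat shock and stress genes, 1 rose (gcs-1), 1 fell (hsp-3) and 12 were not called, and 1 rose and 1 fell adjusted over the list alone. The heat shock list had a median log2 fold change of 0.34, adjusted p = 0.310 and adjusted p = 0.700 with an estimated correlation. The heat shock list was not called in any of the 6 comparisons over all runs, and the sperm list had fewer than 5 members with enough counts in each of them and was not tested. In all, 704 of 5288 genes tested were higher in T7 and 826 lower. Relative log expression size factors moved the median log2 fold change of all genes by -0.19 and gave 618 higher and 1118 lower, and DESeq2 gave 636 and 1158. Within run 1, which held 18 and 25 of the embryos, 703 were higher and 617 lower, and col-121, lpr-5, hch-1 and dpy-3 had too few counts to be tested. Named genes that moved by more than 1.5 times as folds had log2 fold changes of -8.61 for ifa-3 and -6.84 for lpr-3 there, and of -10.08 for col-121, -8.73 for ifa-3, -7.99 for hch-1, -6.86 for lpr-3 and -6.20 for dpy-3 with run as a covariate.

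**Figure D3:**
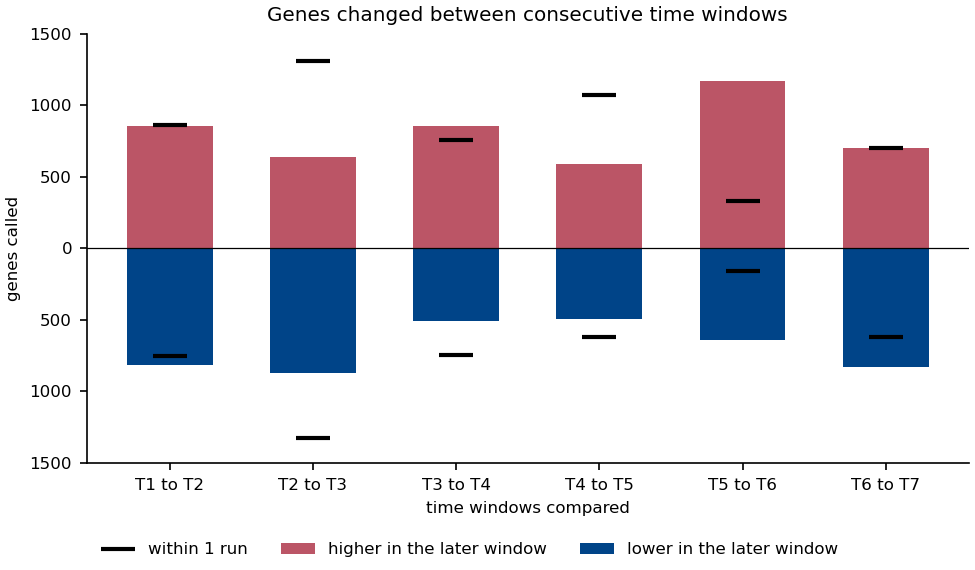
Number of genes called between consecutive time windows, higher in the later window above 0 and lower below 0, as bars for all embryos and as black marks within run 5 (run 1 for T6 to T7). From T5 to T6 the bars reach 1171 and 639 genes and the marks within run 5 lie at 328 and 158.

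The shares of counts followed the same order. Maternal regulators took 2.33 ± 0.779% of gene counts in T1 and 0.319 ± 0.255% in T4 (SD over embryos). Their share was 0.370 ± 0.464% in T5, 0.473 ± 0.326% in T6 and 0.430 ± 0.422% in T7. Early zygotic regulators were highest in T2 at 0.952 ± 0.464%, tissue regulators in T5 at 0.415 ± 0.113% and Hox genes in T4 at 0.0729 ± 0.0245%. Replication and mitosis genes went from 3.01 ± 0.521% in T2 to 0.185 ± 0.164% in T7, and ribosomal protein genes from 2.05 ± 1.09% in T1 to 12.1 ± 1.24% in T7. Muscle genes went from 0.238 ± 0.166% to 4.35 ± 0.948%, cuticle collagens from 0.227 ± 0.308% to 6.70 ± 1.91%, neuropeptides from 0.0573 ± 0.0317% to 0.958 ± 0.456% and pharyngeal genes from 0.00397 ± 0.00658% to 0.875 ± 0.284%. Epidermal junction genes were highest in T5 at 1.06 ± 0.223% and cilium transport genes in T6 at 0.104 ± 0.0374%. Programmed cell death genes went from 0.253 ± 0.0687% in T4 to 0.0715 ± 0.0289% in T7. These shares carry no test of their own, and a share falls when others rise.

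**Figure D4:**
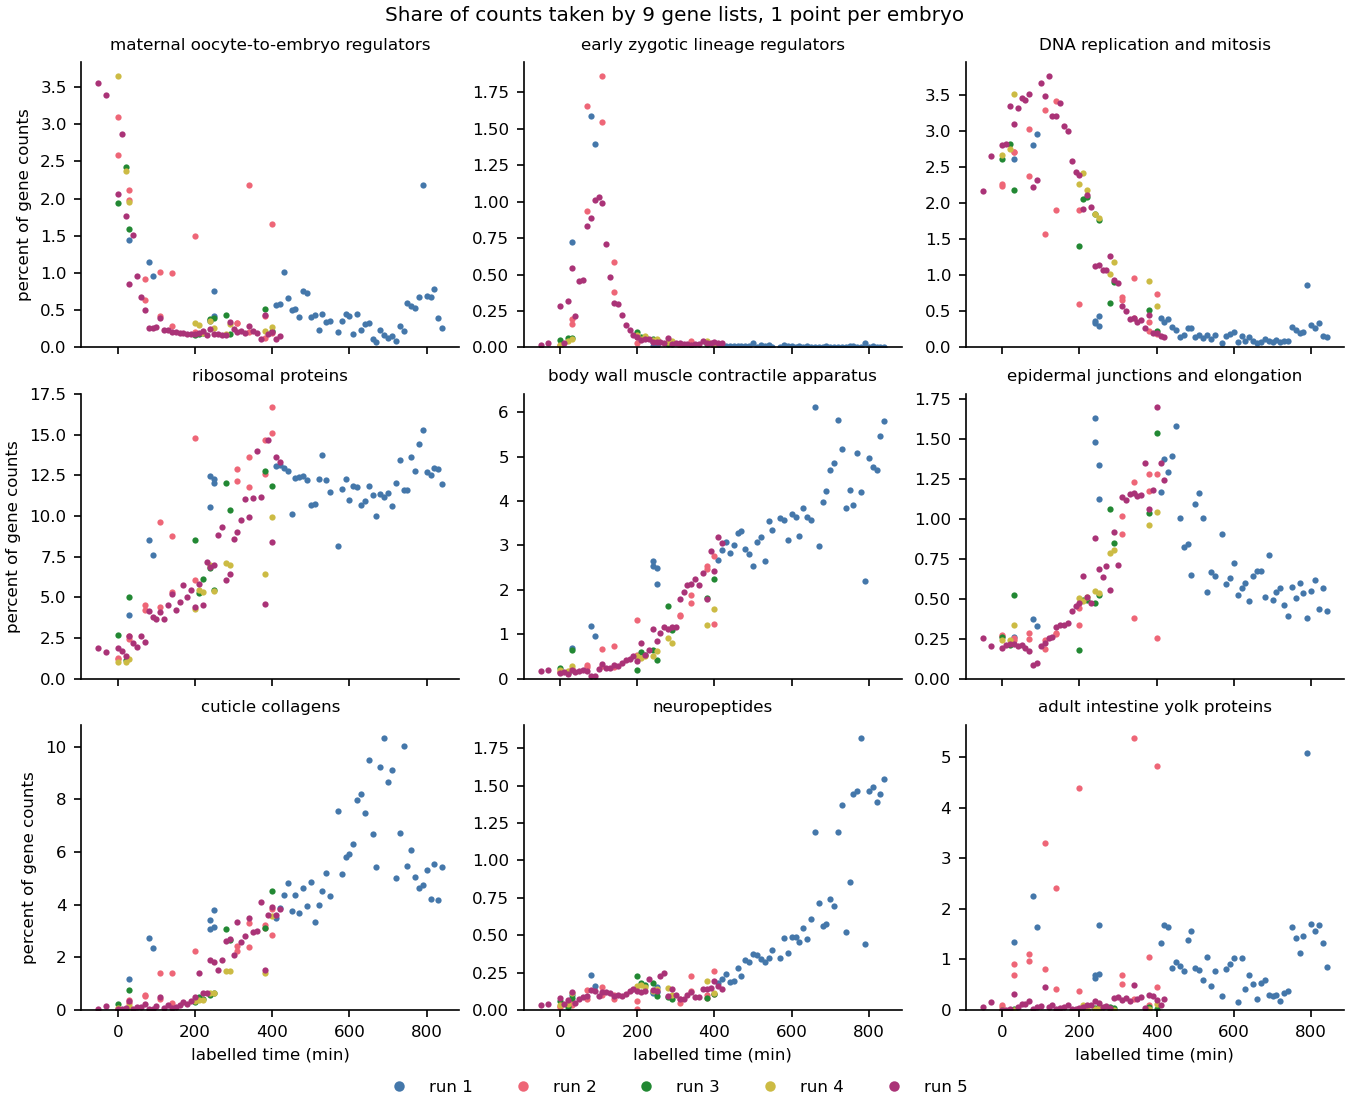
Percent of gene counts taken by 9 gene lists against labelled time in minutes, with 1 point per embryo coloured by run and every vertical axis starting at 0. Early zygotic regulators average 0.952% in T2 and 0.00533% in T7, and yolk protein genes reach 5.37% in an embryo of run 2.

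Genes on the X chromosome took a growing share of counts until T4. Among counts of genes on the 5 autosomes and the X, the X-linked share was 5.10 ± 1.23% in T1, 7.88 ± 1.87% in T2, 12.1 ± 1.43% in T3 and 14.1 ± 1.17% in T4 (SD, n = 17, 11, 13 and 30). Each step passed its two-sided permutation test, with a rise from T1 to T2 by 2.78 ± 0.637 points (SE, p = 0.00014, Benjamini-Hochberg over 6 tests p = 0.00028), T2 to T3 by 4.19 ± 0.688 points (p = 2e-05, adjusted p = 0.00012), and T3 to T4 by 2.02 ± 0.449 points (p = 4e-05, adjusted p = 0.00012). The p of T2 to T3 is the smallest that these permutations can give. The later means were 14.0, 14.1 and 14.2%, with no step past the threshold (differences of -0.106 ± 0.473, 0.160 ± 0.490 and 0.0945 ± 0.311 points, p = 0.829, 0.755 and 0.763, adjusted p = 0.829 each). Within run 5 the share rose from T2 to T3 by 5.38 ± 0.847 points and from T3 to T4 by 2.35 ± 0.453 points (exact permutation tests, adjusted p = 0.00105 and 0.00104), and the difference from T1 to T2 was 2.53 ± 0.960 points (6 and 7 embryos, exact permutation p = 0.028, adjusted p = 0.0559). The median log2 CPM of X-linked genes minus that of autosomal genes, a measure that gives each gene the same weight, was not past the threshold from T1 to T2 or from T2 to T3 (differences of 0.24 and 0.10), rose by 0.41 from T3 to T4 (adjusted p = 0.00208), by 0.30 from T4 to T5 and by 0.21 from T5 to T6, and fell by 0.17 from T6 to T7, and without the 50 most abundant genes the share rose by 0.903 points from T5 to T6.

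**Figure D5:**
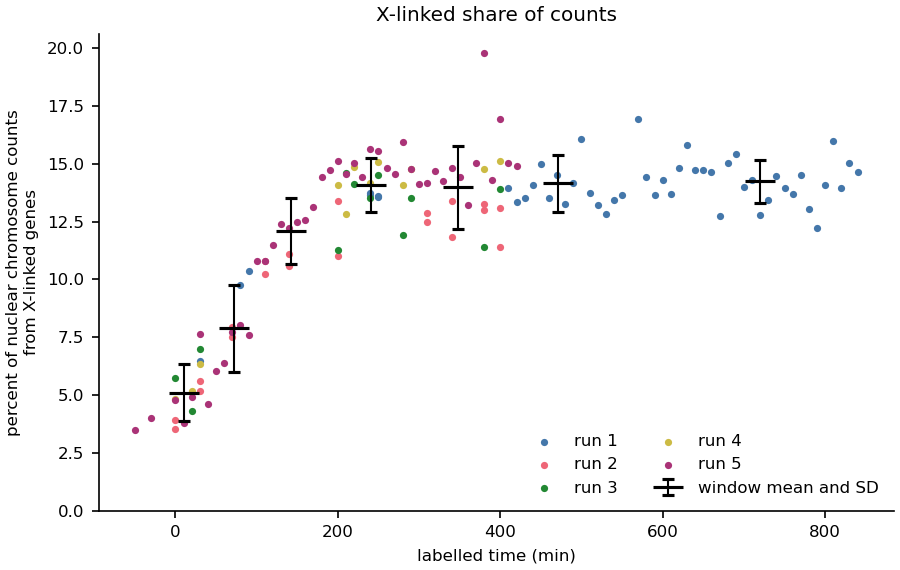
Percent of counts from X-linked genes among genes on the 5 autosomes and the X against labelled time in minutes, with 1 point per embryo coloured by run and black bars at the mean and SD of each window. Window means go from 5.10% in T1 to 14.1% in T4 and lie between 14.0 and 14.2% from T5 to T7.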

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

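The tests chosen only after the result was seen were that of the spike-in share of 3 libraries, the 7 counts of splits and the fits without the 4 embryos or the 3 libraries; the others of this part were written before. Reads outside the comparisons came to 44.08% of all reads with no alignment, 8.357% aligned outside annotated genes and 0.1674% on ERCC spike-in RNA. With no control samples any share above 0 is listed here, which tests nothing about the source of the reads.

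4 run-1 embryos, labelled 240, 240, 250 and 250 min, were predicted at 420, 420, 430 and 430 min. References from other runs placed them at 360 to 390 min (median error 125 min). They placed other run-1 embryos labelled up to 450 min within 20 min. This argues against a run-1 profile as sole cause. Added RNA of older embryos to embryos of the labelled age, with no less than equal parts from the labelled age, is argued against by 94 genes that fell at least 4-fold from T4 to T5 within run 5, whose median log2 ratio to T4 was -3.60 in the 4 embryos. The 473 genes that rose at least 4-fold lay at a median log2 ratio of 0.207 to their level in T5. This restates the embryos' late profiles. A single wrong set of labels or an error in staging stays open, and so does a biological difference, which was not tested.

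3 libraries of run 2, labelled 200, 340 and 400 min, correlated with no reference profile above 0.566. Shallow sequencing alone is argued against by thinning: of 135 other libraries cut to 17878 gene counts the lowest reached 0.588. The spike-in shares of the 3 were 14.9, 6.17 and 5.23% of gene and spike-in counts. The lowest was 7.90 times the highest of the other 17 run-2 libraries, 0.663%, as with little embryo RNA. Of their reads 84.8, 87.2 and 73.6% did not align. The run-1 embryo labelled 790 min, in T7, had pos-1 at 4361 CPM and no rab-3 counts, so 790 min need not be a stage. No biological explanation was tested.

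Random splits exclude chance as the source of the counts of genes called between windows, but they ignore run, which is partly confounded with window. Among random splits of the same embryos into groups of the same sizes only the real one, 1 of 100, gave as many genes for each of the 6 comparisons. From T1 to T2 the real count was 1669 genes and the highest of the other splits 136, from T2 to T3 1508 and 106, and from T3 to T4 1365 and 295. From T4 to T5 they were 1080 and 1, from T5 to T6 1810 and 0, and from T6 to T7 1530 and 0. With run as a covariate 196 genes were higher and 19 lower from T5 to T6, 209 of them among the 1810, and 218 of the 1810 turned sign. That fit rests on embryos of T6 labelled 400 to 420 min, against 400 to 590 min over all runs, so it does not separate run from age. For the 7 windows together 1 of 40 splits, the real one, gave as many as 9304 genes, and the highest of the others gave 484.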

How the results depend on the processing

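The fits within 1 run for the lists, those without the 4 embryos of run 1 or the 3 libraries of run 2, and the similarity without the 2 embryos farthest from the median time were chosen only after the data were seen, and all other alternatives were planned. Of the values that answer a comparison, 134 kept their direction and side of the threshold, or stayed within 1.5 times, under their alternatives, 35 moved further, 2 turned sign, 3 lost their call and 2 gained one. Of the values of named genes 1007 kept theirs, 25 lost their call and 3 turned sign. Of those of lists 361 kept theirs, 60 lost their call, 12 gained one and 4 turned sign, and 90 of marker genes kept theirs. Where no cause is given below, the cause was not tested. Without the low-count filter more genes were tested: 16103 differed among windows, with 3450 higher in T2, 1242 and 1759 higher and lower in T3, 2372 and 1628 in T4, 1951 and 1392 in T5, 3370 and 1582 in T6, and 2871 and 2465 in T7. With an estimated correlation 0 lists were called in each of the 6 comparisons (T1 to T2, T2 to T3, T3 to T4, T4 to T5, T5 to T6, T6 to T7), against 54 of 108 tests with the preset one, and 16 of the 108 had an unadjusted p under 0.05. Adjusted p then ran from 0.160 to 0.987. Within 1 run 1307 genes were higher and 1323 lower in T3, with 8 lists called, 1072 were higher in T5, and 328 were higher and 158 lower in T6. Lists from T5 to T6 then had medians of -0.46 (maternal regulators), -0.67 (collagens), 0.14 (epidermal junctions) and -0.44 (yolk proteins), the opposite sign to all runs together. With run as a covariate 1138 genes were higher in T5 and 196 higher and 19 lower in T6. The log2 fold changes from T5 to T6 of cut-3, F33D4.6 and col-138 were then -0.53, -1.09 and -0.93. T6 holds 18 embryos of run 1, labelled 410 to 590 min, and 7 of other runs, labelled 400 to 420 min, and run 1 has none in T5. The fits within run 5 and with the covariate therefore cover a smaller step in age from T5 to T6, and run is not separated from age there. Without embryos within 20 min of the boundary 1024 genes were higher in T3, 767 lower in T4 and 1485 lower in T6. Without a fold threshold, which can only add genes, 846 were lower in T4 and 741 lower in T5. With DESeq2 761 genes were lower in T5 and 1052 lower in T6. Without the 4 embryos of run 1, 1127 genes were higher in T5. For the X chromosome, the share without the 50 most abundant genes rose by 0.903 points from T5 to T6, and within run 5 the difference from T1 to T2 was 2.53 points, with 6 and 7 embryos. By median log2 CPM of X-linked minus autosomal genes the differences were 0.24 from T1 to T2, 0.10 from T2 to T3, 0.41 from T3 to T4, 0.30 from T4 to T5, 0.21 from T5 to T6 and -0.17 from T6 to T7. In data simulated after T2 and T3, 18 of 100 genes changed 2-fold were called, and whether depth or the spread between embryos limits this was not tested.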

Other observations

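The tests of the lists other than collagens and of single genes against the yolk share were chosen only after the values were seen, and the test of the collagens was written before. Gene families were picked for members among the largest changes, so they carry no test. From T1 to T2, 46 of the 104 fbxb genes in the table, a family of F-box genes, had enough counts to be tested, and the 46 rose with log2 fold changes from 2.63 to 7.51 and a median of 4.85, against 806 of 5590 other genes that rose. The low-count filter favours rises. Of the 46, 29 lie on chromosome II, and 46 were called with relative log expression size factors, 45 with DESeq2 and 43 within run 5. From T3 to T4, 10 of 15 tested skr genes, related to the Skp1 subunit of ubiquitin ligases, fell, against 500 of 6266 other genes. From T6 to T7, 4 of 5 tested lipocalin-related lpr genes fell, against 822 of 5283 others, and 3 were called within run 1. Of the ground-like grl genes 3 of 3 tested rose, against 701 of 5285 others, with 2 called within run 1 and 2 with run as a covariate, and of the related grd genes 1 of 2 tested rose. Members of a family can share reads, so they are not independent.

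Among the 170 lincRNA loci, 19 had enough counts to be tested, and all 19 differed among the 7 windows. None had its highest mean in T1, where 2045 of the genes that differed were highest. By window, 2 lincRNAs were highest in T2, 6 in T3, 2 in T4, 4 in T5, 4 in T6 and 1 in T7.

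Transcripts of adult yolk protein genes varied between runs. Their share of counts in T4 was 0.0318 ± 0.0279% in 7 embryos of run 3, 0.0255 ± 0.0382% in 7 of run 4, 0.102 ± 0.0629% in 10 of run 5 and 2.37 ± 2.84% in 2 of run 2, 1 of which is among the 3 libraries unlike all others. It was 0.925 ± 0.499% in the 4 embryos of run 1 that resemble later embryos. Over 40 embryos of T1 to T3, after the mean of each run and window was subtracted from the log10 share, the yolk share rose with the share of cuticle collagens (Pearson r = 0.793, permutation p = 2e-05, Spearman rho = 0.819, permutation p = 1e-05, the smallest that the permutations can give). Without the 2 embryos farthest from the median r was 0.797, and it was 0.983 in the 10 embryos of run 2 and 0.757 in the 22 of run 5, while runs 1, 3 and 4 held 2, 3 and 3.

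A candidate explanation is RNA of other worms carried along with the embryo, since yolk proteins are made by adults and many cuticle collagens by larvae and adults. The r of 0.793 lies above 0.5, the value set for this explanation, where 0.2 or less would have spoken against it. Of 19 other lists 4 passed the threshold: collagens, intestine (r = 0.744), pharynx (r = 0.741) and body wall muscle (r = 0.521), with Benjamini-Hochberg p = 0.000317 for the first 3 and 0.00332 for the last, while r was 0.160 for maternal regulators. Of 7747 genes 106 had r above 0.6 and 2 below -0.6. The 106 include the 6 yolk protein genes that make up the share, whose r says nothing about its source. Among the highest of the others were 0.92 for col-181 (314 ± 509 CPM), 0.91 for perm-2 (239 ± 449 CPM), 0.91 for far-2 (409 ± 793 CPM), 0.91 for asp-1 (204 ± 383 CPM) and 0.83 for col-19 (185 ± 343 CPM), a collagen of the adult cuticle. The embryo also expresses collagens itself, with 84 of the 176 in the list tested from T6 to T7, and a biological source in the embryo stays open.

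1 embryo of run 4 labelled 380 min was predicted at 280 min, the largest error besides the 7 over 100 min.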
